A study of Danio rerio with 12 samples.

How the data were processed

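Whole hearts of wild-type and yap mutant zebrafish were collected 7 days after sham surgery or cryoinjury. Per the labels' protocols, RNA was extracted with Trizol, its quality was read on a BioAnalyzer, and libraries were made with a low-input poly-A kit for the BGISEQ-500 platform. Per the submitters' processing notes, HISAT and Bowtie2 were used with the genome build GRCz11. Their versions, their order and the program that made the expression values are not given in the sources used here. The authors deposited FPKM values (fragments per kilobase of transcript, scaled to the library's mapped fragments), 1 value per gene and library, with NCBI gene identifiers and symbols. FPKM corrects for transcript length and library total, but where a few abundant transcripts take a larger share, the values of all others fall. The libraries' FPKM sums differ, so the values are not TPM.

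Groups were taken from the labels: 4 groups of 3 libraries each. Of the value columns, 13 matched a sample by name and were used, and 1 matched none and was not used. Mutant sham 3 had 2 columns, whose values were averaged and counted as 1 sample. The file lists 24782 genes, some of them without a symbol, and those with a mean FPKM of 1 or more over the 12 samples were tested (13969). Names were used as the file gives them and older names were matched through a RefSeq gene table of the assembly GRCz12tu, from which no coordinates were taken because the builds differ. Reads of near-identical paralogs, such as the keratin, globin and parvalbumin genes, could have been divided between copies in ways that are not given in the sources used here.

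Values were tested as log2(FPKM + 1), which understates the change of low genes, in R 4.3.3 with limma 3.58.1 (a mean per group over all 12 samples, moderated with an intensity trend) and Benjamini-Hochberg adjustment at 0.05. The contrasts fixed in advance were cryoinjury against sham in each genotype, mutant against wild type in each injury, the difference of the injury responses, and mutant against wild type over both injuries. Cryoinjury against sham over both genotypes was added after the values had been seen. yap1 and wwtr1 were also compared by an exact permutation of genotype within injury, two-sided. With 3 libraries against 3 an exact test cannot go below p = 0.10, so single contrasts of 2 groups rest on limma.

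Of 33 gene lists fixed in advance, 30 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01. camera was repeated with an estimated correlation, whose median over lists was 0.348, and fry was run as a further test. fry asks whether a list's genes move, on balance, one way, and does not compare them with other genes. The lists cover targets of Yap and Taz, Hippo pathway components, cell types of the heart and its blood, metabolism, proliferation, immune and stress responses, signalling, and tissues that can adhere to a dissected heart. The lists of mitochondrially encoded mRNAs, of gonad and female plasma proteins, and of neural and pigment cells had too few tested members, the first of them 0. Some genes stand in more than 1 list, as myl9a and myl9b do among Yap and Taz targets and smooth muscle genes. The keratins are divided between the epicardial and the skin list.

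Genes were named by a fixed rule. The rule takes yap1 and wwtr1, then called genes with a proper symbol, a mean FPKM of 5 or more in the higher group and no overlap between libraries (the 10 largest rises and falls), then up to 4 members of each list with the lowest p, and, where nothing was called, the 5 genes with the lowest p. A gene named in 1 contrast may be followed through the others. Of the genes that the rule takes, 1 is not reported here.

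Depth was not recorded in the values, but FPKM of low genes are multiples of the worth of 1 fragment. The steps between values of 0.3 to 1.5 FPKM gave the relative depth of 78 pairs of columns, and 70 of them lay within 0.03 (log2) of the joint solution. Tested on simulated data for cryoinjury against sham in wild type (13969 genes, 10 simulations), limma called 33.6% of genes changed 2-fold, 80.4% changed 4-fold, 93% changed 8-fold and 97.2% changed 16-fold, and 0.0668% of unchanged genes. The changed genes were drawn from those with a mean of 5 FPKM or more, the lower of them changed upward only. The rates therefore do not cover genes of 1 to 5 FPKM. The changed genes were also drawn at random, so the rates describe genes of typical spread and would be lower for genes that vary more. The median SE of all tested genes in that contrast was 0.278 (log2). A 2-fold shift of the macrophage list was called in 10 of 10 simulations, and 0 of 290 unshifted lists. The simulated genes vary independently, which real genes of 1 cell type do not.

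The groups, contrasts, gene lists, naming rule and the settings listed next were chosen before the data were examined. Results were also computed with a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-of-ratios rescaling, rescaling to a common sum (TPM), quantile normalization, the replicate number as a block, only the 2 groups compared, array weights, an added log2 limit of 1, and without each library in turn. Leaving out mutant sham 1 and 2 together, robust moderation, and an exact permutation of list means were added after the data had been seen. Further tools were the R package data.table at version 1.17.8, Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.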

Results

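Polyadenylated RNA was profiled in 12 libraries of whole zebrafish (Danio rerio) hearts taken 7 days after an operation on the ventricle. The fish were 6 to 12 months old and carried either yap +/+ (wild type) or yap -/- (mutant). The gene yap1 encodes Yap, a transcriptional co-activator that the Hippo kinases hold back. Cryoinjury kills the ventricular tissue touched by a steel probe chilled in liquid nitrogen, and in sham hearts the ventricle was exposed and left alone. Each of the 4 combinations of genotype and injury had 3 libraries, called here by genotype, injury and replicate number. The design asks how hearts respond to injury with and without yap1, and how mutant and wild-type hearts differ in each state. The labels do not say that replicates came from separate animals, nor whether hearts were pooled, so p-values measure the spread between these samples.

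The values are FPKM, and total reads per library were not used here. The steps between the values of low genes gave the depth relative to wild-type sham 1. It ran from 0.816 times in mutant cryoinjury 1 to 1.32 and 1.38 times in the 2 columns of mutant sham 3. Summed FPKM ran from 668670 in wild-type sham 2 to 823110 in wild-type sham 3. Between 3145 genes (wild-type cryoinjury 3) and 5138 genes (mutant sham 1) of 24782 were listed at 0. The 2 columns of mutant sham 3 had a median absolute log2 difference of 0.02, against 0.21 to 0.67 between replicates of a group. They were averaged and counted as 1 sample.

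yap1 (NCBI gene 561411) was lower in every mutant library than in every wild-type library. It stood at 26.0 ± 4.48 FPKM (SD, n = 6, range 18.8 to 29.8) in wild type and at 12.9 ± 1.65 FPKM (SD, n = 6, range 10.1 to 14.4) in mutants. The mean log2 difference was -0.95 (exact permutation of genotype within injury, two-sided p = 0.005, the smallest that the 400 arrangements can give). Without any single library the difference lay between -1.05 and -0.87. The transcript was still measured in all 6 mutant libraries. In sham hearts yap1 was at 25.2 ± 5.57 FPKM in wild type and 12.9 ± 2.43 FPKM in mutants, and in cryoinjured hearts at 26.8 ± 4.14 and 12.8 ± 0.965 FPKM (SD, n = 3 each). wwtr1 (NCBI gene 568008), which encodes the paralogous co-activator Taz, was at 15.6 ± 2.45 FPKM in wild type and 14.0 ± 2.66 FPKM in mutants (exact permutation p = 0.28, n = 6 each). yap1 differed little between cryoinjury and sham, by 0.10 ± 0.22 (log2, SE) in wild type and 0.00 ± 0.22 in mutants, and the sign of these small values turned with the scaling, to -0.14 and -0.04 with median-of-ratios rescaling.

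**Figure D1:**
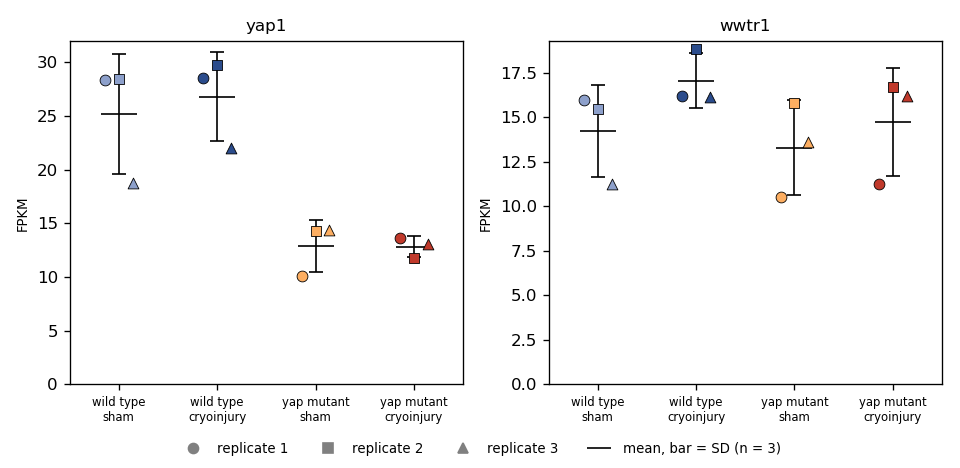
FPKM of yap1 and wwtr1 in each of the 12 libraries by group; points are libraries, bars are means with SD, n = 3. yap1 in the mutant libraries lies between 10.1 and 14.4 FPKM and in the wild-type libraries between 18.8 and 29.8 FPKM.

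The libraries did not separate by group alone. On the first principal component, with 29.4% of the variance, wild-type sham libraries lay between 4.26 and 28.0 and wild-type cryoinjured ones between -28.8 and -13.5. The mutant sham libraries spanned the whole axis, at 74.7 (mutant sham 1), -41.7 (mutant sham 2) and 2.22 (mutant sham 3). The mean correlation between libraries of a group was 0.941 ± 0.021 (SD over 12 pairs), and between groups 0.934 ± 0.018 (54 pairs). It was lowest within mutant sham hearts, at 0.917. Ribosomal protein mRNAs made up 38.8% of summed FPKM in mutant sham 1 and 32.0% in mutant cryoinjury 2, against 13.3% to 20.3% in the other 10 libraries. Globin mRNAs, which come from red blood cells, made up 3.84% (wild-type sham 1) to 30.7% (wild-type sham 3). In mutant sham 2 the macrophage genes averaged 2.17 (log2) above wild-type sham hearts and the fibrillar matrix genes 1.86. The cryoinjured wild-type libraries stood at 0.96 to 1.5 and 1.17 to 1.83 on the same scales, and mutant sham 1 at -0.31 and -0.93.

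**Figure D2:**
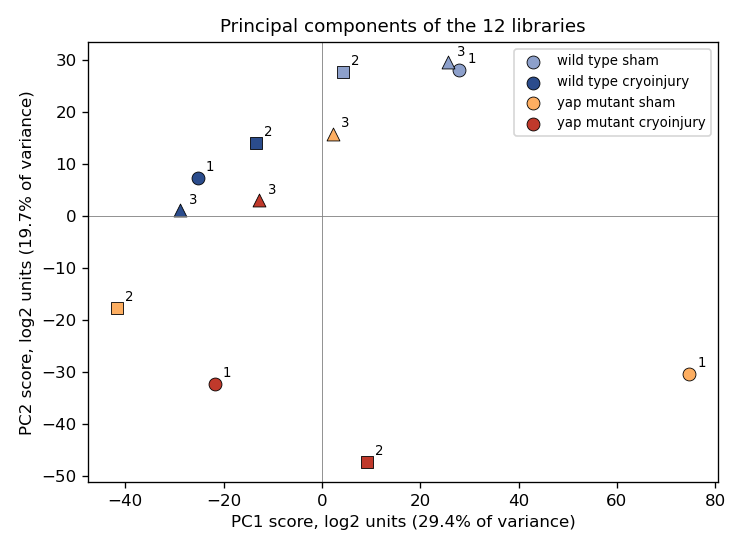
Scores of the 12 libraries on the first (29.4% of variance) and second (19.7%) principal components of log2(FPKM + 1) over tested genes, coloured by group. Mutant sham 1 lies at 74.7 and mutant sham 2 at -41.7 on the first component, on opposite sides of all other libraries.

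The comparison of cryoinjured with sham hearts in wild type describes the injury response with yap1 intact. The genes with the lowest p all stood higher after injury, with no overlap between libraries (10% of genes by chance, and favoured by choosing the lowest p). lipg (NCBI gene 393096), encoding endothelial lipase, went from 0 to 0.46 FPKM in the sham libraries to 2.49 to 5.14 FPKM. adam8a, a membrane metalloproteinase found on leukocytes, went from 0.663 ± 0.43 to 12.3 ± 4.96 FPKM (2.95 ± 0.45 log2, SE). nupr1, a stress-induced nuclear protein, went from 7.44 ± 2.22 to 30.0 ± 7.35 FPKM, and il21r.1, a cytokine receptor gene, from 0.307 ± 0.156 to 2.56 ± 0.24 FPKM. None of these 4 passed limma with Benjamini-Hochberg adjustment over 13969 genes (adjusted p 0.14 to 0.185, n = 3 each). In all 0 genes passed, against 1211 at an unadjusted p under 0.05 (1097 higher and 114 lower), where 698 would be expected by chance. Without mutant sham 1, which enters only through the shared spread and the filter, 18 genes passed, and without wild-type sham 1, 1 did. With only the 2 groups compared 8 passed, with array weights 409, and with mutant sham 1 and 2 both left out 34.

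Scar and scavenger genes stood out among the gene lists, which were tested with camera against the rest of the genes. All 35 measured genes of fibroblasts and fibrillar extracellular matrix were higher after injury (median 1.52, adjusted p 2.44e-13), 13 of them when adjusted over the list alone. timp2b, a metalloproteinase inhibitor, went from 4.97 ± 1.21 to 29.7 ± 9.77 FPKM and col12a1a, a fibril-associated collagen, from 4.79 ± 4.07 to 49.7 ± 25.1 FPKM. Of the epicardial genes, which mark the sheet covering the heart, 18 of 19 were higher (median 1.02, 1.03e-06, 4 adjusted over the list alone), among them clu, encoding the secreted chaperone clusterin, from 27.8 ± 10.5 to 191 ± 117 FPKM, and the Wilms tumour factor wt1b from 4.28 ± 0.546 to 13.9 ± 1.04 FPKM. Macrophage genes (28 of 29 higher, median 1.33, 5.85e-09), pan-leukocyte genes (24 of 24, median 1.0, 1.16e-07) and cell cycle genes (41 of 41, median 0.96, 6.99e-08) had no member passing when adjusted over the list alone. Their members included the macrophage-expressed receptor havcr1, from 4.82 ± 1.14 to 15.6 ± 2.74 FPKM, lcp1, a leukocyte actin-bundling protein, from 7.87 ± 4.21 to 30.5 ± 10.2 FPKM, and ccnb1, mitotic cyclin B1, from 2.14 ± 0.671 to 6.63 ± 1.43 FPKM. With an estimated correlation the adjusted p of these 5 lists was 0.465 to 0.568, so none of the calls held in that test.

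The energy and contraction genes of heart muscle lay on the other side. Of the 56 nuclear-encoded genes of oxidative phosphorylation, 51 were lower (median -0.39, adjusted p 2.2e-32), as were 29 of 31 genes of fatty acid oxidation (median -0.30, 1.81e-10) and 27 of 33 genes of sarcomere and calcium handling (median -0.24, 1.65e-09). ndufa5, of respiratory complex I, went from 324 ± 49.3 to 203 ± 4.55 FPKM. cpt1ab, which takes long-chain fatty acids into mitochondria, went from 83.4 ± 10.4 to 54.9 ± 5.68 FPKM, and ldb3b, a Z-disc protein gene, from 1334 ± 143 to 818 ± 107 FPKM. Glycolysis genes were called lower as a list (median -0.33, 3.49e-06), though the enolase eno1b was higher by 0.79 ± 0.24. The glycolysis median was -0.19 without wild-type sham 1, -0.04 without wild-type sham 2 and -0.21 without wild-type cryoinjury 3, and the sarcomere median -0.15 without wild-type cryoinjury 3 and -0.36 without wild-type sham 3, with both calls kept. None of these 4 lists had a member passing when adjusted over the list alone, and their adjusted p with an estimated correlation was 0.465. Ribosomal protein genes were called lower (6.32e-06, 0.708 with an estimated correlation) at a median of -0.01. This median was -0.26 with median-of-ratios rescaling, 0.02 with TPM rescaling and 0.09 with quantile normalization. It was -0.08, 0.07 and -0.03 without wild-type cryoinjury 1, 2 and 3, and 0.03, 0.00 and -0.07 without wild-type sham 1, 2 and 3.

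A further 5 lists were called in wild type by margins that single libraries removed. Targets of Yap and Taz were higher (21 of 26, median 0.35, adjusted p 0.0214, 5 adjusted over the list alone, adjusted p 0.701 with an estimated correlation), with thbs1, encoding thrombospondin, at 1.59 ± 0.44 and the kinase gene nuak2 at 0.72 ± 0.20. Their median was 0.15 without wild-type sham 3 (adjusted p 0.419), 0.55 without wild-type sham 2, and 0.35 without mutant sham 1 (adjusted p 0.0515). Complement genes were higher (5 of 7, median 1.51, 0.0391, 5 adjusted over the list alone, 0.558 with an estimated correlation), such as c7a of the membrane attack complex, at 18.1 ± 9.04 and 49.7 ± 6.55 FPKM. That call ended without wild-type cryoinjury 2, wild-type sham 3, mutant cryoinjury 1 or 2, or mutant sham 1 or 3 (adjusted p 0.0520 to 0.134). Antigen presentation genes (median 0.83, 0.0391, 0 adjusted over the list alone, 0.568 with an estimated correlation) lost their call without wild-type cryoinjury 1 or 3, wild-type sham 2 or mutant sham 3 (0.0529 to 0.224). Thrombocyte genes (median 0.51, 0.0260, 1 adjusted over the list alone, 0.568 with an estimated correlation) lost theirs without wild-type cryoinjury 1, wild-type sham 1 or mutant sham 1 (0.0515 to 0.157). Liver and plasma protein genes (median -0.23, 0.0360, 0 adjusted over the list alone, 0.503 with an estimated correlation) lost theirs without wild-type cryoinjury 2, mutant cryoinjury 1 or mutant sham 1, and stood at 0.14 without wild-type sham 3 (0.783). Their median was -0.60 without wild-type sham 1 (0.000443), -0.46 without wild-type sham 2 (0.00400), -0.43 without wild-type cryoinjury 1 and -0.05 without wild-type cryoinjury 3, with the call kept.

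The other 15 lists were not called in wild type. Smooth muscle and bulbus arteriosus genes had a median of 0.37 (adjusted p 0.444), with 2 members passing when adjusted over the list alone. tagln, a smooth muscle actin-binding protein gene, was at 246 ± 20.4 FPKM in sham and 1016 ± 369 FPKM in cryoinjured hearts. Regeneration ligands and factors stood at 0.30 (0.579, 3 adjusted over the list alone), with the growth factor gene mdka higher by 3.31 ± 0.73 (log2, SE). Skeletal muscle genes stood at 0.56 (0.125, 3 adjusted over the list alone), lymphocyte genes at 0.55 (0.408, 1 adjusted over the list alone) and neutrophil genes at 0.10 (0.803, 2 adjusted over the list alone). With 0 such members each, inflammatory mediators stood at 0.60 (0.156), skin and gill epithelium at 0.61 (0.182), erythrocyte genes at 0.61 (0.774), immediate early and heat shock genes at 0.48 (0.520) and interferon response genes at 0.42 (0.415). Hippo pathway components stood at 0.26 (0.395), embryonic and border-zone cardiomyocyte genes at 0.20 (0.541), circadian clock genes at 0.18 (0.861), endothelial and endocardial genes at 0.08 (0.0659), and exocrine pancreas and gut genes at -0.27 (0.184). The median of all tested genes was itself 0.19, and -0.01 after median-of-ratios rescaling, so list changes are relative to that shift. With that rescaling the embryonic, neutrophil and endothelial medians turned to -0.03, -0.10 and -0.14, and the camera direction of these 3 lists was down. The circadian median turned to -0.05 with quantile normalization.

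**Figure D3:**
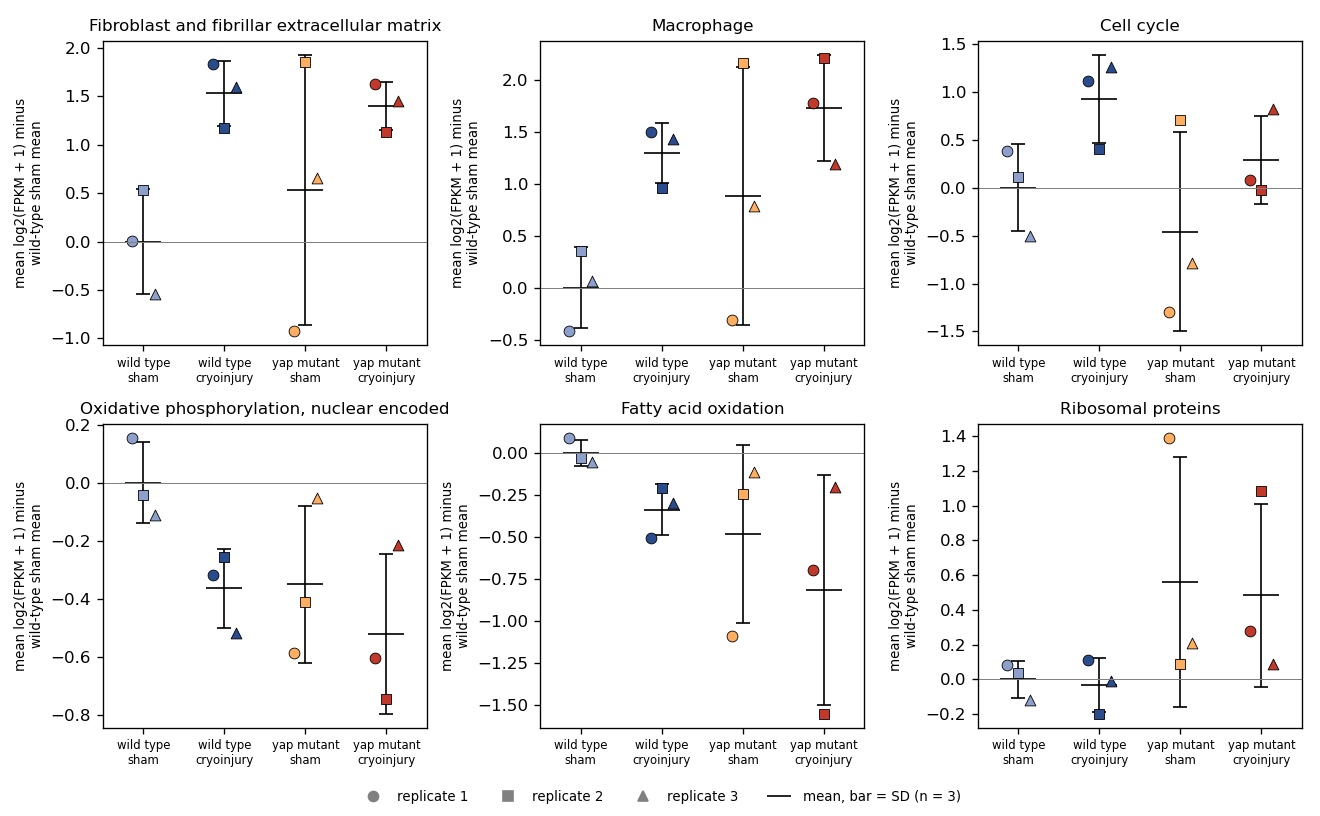
Mean log2(FPKM + 1) of 6 gene lists in each library, minus the mean of the wild-type sham libraries; points are libraries and bars group means with SD, n = 3. Mutant sham 2 stands at 1.86 for matrix genes and 2.17 for macrophage genes, and mutant sham 1 at 1.39 for ribosomal protein genes.

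The same comparison in mutants describes the injury response without intact yap1. lipg and il21r.1 again had the lowest p. lipg was at 0.04 to 0.88 FPKM in sham and 4.53 to 5.94 FPKM in cryoinjured mutants (2.17 ± 0.28 log2, adjusted p 0.0958), and il21r.1 went from 0.96 ± 0.382 to 5.09 ± 1.91 FPKM (1.61 ± 0.24, 0.189). The other 3 genes with the lowest p belong to fast muscle. Skeletal muscle is among the tissues that can adhere to a dissected heart, and here and below adhering muscle was not told apart from a change within the heart. The calcium-binding parvalbumins pvalb1 and pvalb2 went from 1.09 ± 0.315 to 12.4 ± 6.89 FPKM and from 1.94 ± 1.4 to 18.3 ± 9.32 FPKM, and the fast troponin gene tnnt3b from 0.358 ± 0.238 to 9.26 ± 7.71 FPKM. With limma 0 genes passed, against 435 at an unadjusted p under 0.05 (278 higher and 157 lower), fewer than the 698 expected by chance. Without mutant cryoinjury 2, 3 genes passed, and without mutant sham 2, 2 did.

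Among the lists, 14 were called higher and 2 lower in mutants, of which 7 of the 16 calls held without each single library. The 7 were cell cycle (40 of 41 higher, median 0.70, adjusted p 4.5e-12), skeletal muscle (16 of 18, median 1.05, 6.63e-12, 8 adjusted over the list alone), macrophage (27 of 29, median 0.78, 1.88e-09), fibrillar matrix (31 of 35, median 0.81, 7.39e-09, 1 adjusted over the list alone), pan-leukocyte (21 of 24, median 0.78, 5.86e-08), inflammatory mediators (25 of 31, median 0.36, 1.91e-05, 1 adjusted over the list alone) and targets of Yap and Taz (20 of 26, median 0.24, 2.2e-05, 2 adjusted over the list alone). Members included timp2b, from 6.01 ± 6.04 to 27.8 ± 12.1 FPKM, and tyms, the thymidylate synthase that DNA replication needs, from 4.32 ± 5.64 to 10.9 ± 4.29 FPKM. csf1a, a macrophage growth factor, went from 0.448 ± 0.386 to 3.91 ± 2.24 FPKM (1.71 ± 0.36 log2), and ankrd1a, a stretch-induced Yap target, was higher by 2.29 ± 0.62. The adjusted p of all 7 with an estimated correlation was 0.443. Mutant sham 1 and mutant sham 2 pulled these medians apart. The matrix median was -0.06 without mutant sham 1, although the list was still called higher, and 1.49 without mutant sham 2. Without mutant sham 1 and without mutant sham 2 in turn, the macrophage median was 0.22 and 1.52, the pan-leukocyte median 0.19 and 1.53, the cell cycle median 0.35 and 1.28, and the Yap and Taz target median 0.08 and 0.47 (0.39 without mutant cryoinjury 2). The skeletal muscle median was 0.55 without mutant sham 1 and 0.66 without mutant cryoinjury 3, and the inflammatory median 0.24 without mutant cryoinjury 1, 0.68 without mutant cryoinjury 3 and 0.80 without mutant sham 2.

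Genes of fatty acid oxidation and oxidative phosphorylation were also called lower in injured mutants, at medians of -0.33 (adjusted p 2.11e-06, 0.443 with an estimated correlation) and -0.19 (2.08e-06, 0.491 with an estimated correlation), with 0 members passing when adjusted over either list alone. cpt1ab went from 58.2 ± 12.3 to 31.8 ± 6.94 FPKM and cox7a1, a cytochrome oxidase subunit of heart and muscle, from 704 ± 244 to 436 ± 74.7 FPKM. The first median was 0.03 without mutant cryoinjury 2 (adjusted p 0.146), -0.70 without mutant cryoinjury 3 and -0.69 without mutant sham 1. The second was -0.02 without mutant sham 3 (0.152), -0.06 without mutant cryoinjury 2, -0.35 without mutant cryoinjury 3 and -0.29 without mutant sham 1. Sarcomere genes (median 0.01, 0.884) and glycolysis genes (median 0.00, 0.960) were not called, and both medians turned to -0.04 with median-of-ratios rescaling.

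Averaging the injury response over both genotypes, a contrast added after the values were seen, sets 6 cryoinjured against 6 sham libraries. It called 9 genes, all higher after injury. lipg rose by 2.09 ± 0.20 (log2, SE, limma adjusted p 0.00400), il21r.1 by 1.53 ± 0.17 (0.010), adam8a by 2.60 ± 0.32 (0.0165) and nupr1 by 1.59 ± 0.20 (0.0198). The parvalbumin genes pvalb1 and pvalb2, rare in heart muscle and abundant in fast skeletal muscle, rose by 2.19 ± 0.32 and 2.48 ± 0.36 (0.0343 each). Whether their mRNA came from the heart or from adhering muscle was not tested. LOC560295, an uncharacterised locus, and adamtsl7, of the thrombospondin-repeat family, rose as well, by 1.78 ± 0.25 and 1.45 ± 0.22 (0.0299 and 0.0401); both fall outside the naming rule and were taken up after their values were seen. LOC560295 passed only without wild-type cryoinjury 2, mutant cryoinjury 3 or mutant sham 2, and adamtsl7 only without the first or the last of these (highest adjusted p 0.121 and 0.168). At an unadjusted p under 0.05 there were 1355 genes, 1151 of them higher. The call of lipg held without each single library and il21r.1 passed except without wild-type cryoinjury 1 (adjusted p 0.0598) or mutant sham 3 (0.0561). Leaving out any library except mutant cryoinjury 2 or mutant sham 2 ended at least 1 of the calls of adam8a, nupr1, pvalb1 and pvalb2, with a highest adjusted p of 0.0852 to 0.146 per gene. The number of called genes depended on single libraries. It was 1, 7 and 2 without wild-type cryoinjury 1, 2 and 3, and 3, 5 and 3 without wild-type sham 1, 2 and 3. It was 2, 12 and 5 without mutant cryoinjury 1, 2 and 3, and 5, 428 and 1 without mutant sham 1, 2 and 3. It was 3 with the replicate block and 290 with array weights.

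Mutant sham 2 accounted for most of that range. The 100 genes with the lowest p for cryoinjury against sham over both genotypes were chosen without the library in question. In mutant sham 2, 87 of them lay nearer the cryoinjured than the sham level. The other 5 sham libraries had 7 to 26 such genes and the 6 cryoinjured ones 60 to 90. Without it, 418 genes rose and 10 fell over both genotypes, all 9 of the genes called with 12 libraries among them, with 13855 genes tested. The library was singled out because its injury genes ran against this contrast, so the larger number is no independent measure of the response. In those 11 libraries mdka went from 50.6 FPKM in sham to 386 FPKM in cryoinjured hearts, timp2b from 4.04 to 28.8 FPKM, fibronectin gene fn1a from 3.76 to 29.0 FPKM, wt1b from 5.77 to 19.7 FPKM and clu from 22.6 to 155 FPKM. cox7a1 was among the 10 that fell, from 737 to 409 FPKM. The adjusted p of the lists with an estimated correlation was still 0.292 or more. With all 12 libraries, 22 of 30 lists were called (15 higher and 7 lower), 14 of which held without each single library, and with an estimated correlation 0 were (smallest adjusted p 0.343).

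**Figure D4:**
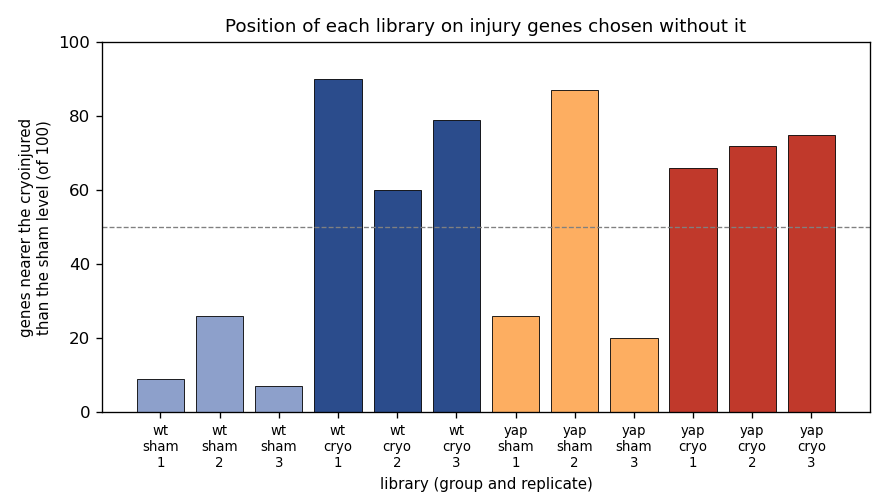
For each library, the number of 100 injury genes, chosen by lowest p over both genotypes without that library, that lay nearer the cryoinjured than the sham level. The dashed line is at 50. Mutant sham 2 has 87, the other sham libraries 7 to 26 and the cryoinjured libraries 60 to 90.

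The injury responses of both genotypes were correlated. Their log2 changes, which share no libraries, had a Pearson r of 0.484 and a Spearman rho of 0.408 across 13969 genes, which are not independent replicates. Of the 1211 genes at an unadjusted p under 0.05 in wild type, 82.4% had the same sign in mutants, against 60.9% of all tested genes. The mutant change of these 1211 genes was smaller, with a slope of 0.466 on the wild-type change and a median ratio of 0.376. Choosing genes by their wild-type p by itself favours a slope under 1. The mutant change also rests on uneven sham libraries. Over 100 wild-type injury genes, mutant sham 2 stood at 1.05 between wild-type sham (0) and wild-type cryoinjury (1), and mutant sham 1 at -0.206. The former lowers the mutant change and the latter raises it, and no slope without either is given here. For 160 genes both responses had an unadjusted p under 0.05 and the same sign, where independent lists would give 23.1. The lists are not independent, because both p-values use the same estimate of each gene's spread. Genes of low spread tend to pass in both, so 23.1 may understate chance. The r was 0.238 without mutant sham 1 and 0.563 without mutant sham 2.

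No gene passed the test of the difference between the responses (limma, smallest adjusted p 1.0), against 271 at an unadjusted p under 0.05, where 698 would be expected by chance. Without wild-type sham 1, 1 gene passed. The lowest p belonged to cdkal1, a tRNA-modifying enzyme gene, at -0.91 ± 0.26 (log2, SE), followed by hexa, a lysosomal hexosaminidase, at -0.90 ± 0.27, ndst3 of heparan sulfate synthesis at -1.45 ± 0.43, phyhd1 at 1.45 ± 0.45 and the cell cycle inhibitor cdkn1a at -1.02 ± 0.32. cdkn1a went from 5.71 ± 0.648 to 15.5 ± 3.14 FPKM in wild type and from 6.56 ± 1.47 to 8.05 ± 1.78 FPKM in mutants. tagln went from 246 ± 20.4 to 1016 ± 369 FPKM in wild type and from 233 ± 93.3 to 402 ± 184 FPKM in mutants, a difference of -1.23 ± 0.55. Of the lists, 8 were called, 7 towards higher and 1 towards lower values, and with an estimated correlation 0 were (smallest adjusted p 0.740). The 3 calls that held without each single library were oxidative phosphorylation (50 of 56 positive, median 0.19, 1.73e-12), sarcomere and calcium handling (27 of 33, median 0.21, 6.31e-08) and skeletal muscle (14 of 18, median 0.35, 1.5e-06), each with adjusted p 0.740 with an estimated correlation and 0 members passing when adjusted over the list alone. The oxidative phosphorylation median ranged from 0.02 without mutant cryoinjury 3 and 0.05 without mutant sham 1 to 0.33 without mutant cryoinjury 2 and 0.35 without mutant sham 3, and was 0.12 without wild-type cryoinjury 3 or wild-type sham 1. The sarcomere median was 0.03 without mutant sham 1, 0.06 without mutant cryoinjury 3, 0.32 without wild-type sham 3, 0.39 without mutant sham 3 and 0.47 without mutant cryoinjury 2. With mutant sham 1 and 2 both left out, the oxidative phosphorylation and sarcomere medians were -0.12 and -0.07 and neither list was called (adjusted p 0.359 and 0.150). The skeletal muscle median was 0.15 without mutant sham 1, 0.18 without wild-type cryoinjury 3 and 0.21 without mutant cryoinjury 3. It was 0.54 without wild-type sham 2, 0.61 without mutant sham 3, 0.68 without wild-type cryoinjury 1 or mutant sham 2, and 0.97 without mutant cryoinjury 2.

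In sham hearts, mutants differed from wild type first in a keratin. krt15 (NCBI gene 406844), of the intermediate filaments of epithelia, was at 249.8 ± 33.8 FPKM in wild type and 756 ± 52.1 FPKM in mutants (1.60 ± 0.24 log2, SE, limma adjusted p 0.256). slc16a1a, a monocarboxylate transporter gene, was at 11.3 ± 7.45 FPKM in wild type and 0.337 ± 0.197 FPKM in mutants (-3.05 ± 0.48, 0.256). mfng, which modifies Notch receptors, was at 2.86 ± 2.07 and 18.7 ± 7.84 FPKM, the transcription factor gene cebpa at 4.80 ± 1.67 and 15.3 ± 6.65 FPKM, and the adhesion gene jam2b at 1.99 ± 0.866 and 7.70 ± 1.2 FPKM. None of these 5 passed. The 3 libraries of each genotype did not overlap for any of them. Chance gives this for 10% of genes, and choosing the lowest p favours it. limma called 0 genes, against 837 at an unadjusted p under 0.05 (565 higher and 272 lower), where 698 would be expected by chance. Without mutant cryoinjury 3, 2 genes passed, and without wild-type sham 1, 1 did.

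Of the lists, 9 were called higher and 7 lower in mutant sham hearts, and 8 of the 16 calls held without each single library. Lower among these were oxidative phosphorylation (53 of 56 lower, median -0.35, adjusted p 7.06e-15), sarcomere and calcium handling (30 of 33, median -0.54, 1.49e-11), fatty acid oxidation (29 of 31, median -0.48, 1.93e-08) and cell cycle genes (36 of 41, median -0.44, 1.91e-06), none with a member passing when adjusted over the list alone. mybpc3, cardiac myosin-binding protein C, was at 1460 ± 181 FPKM in wild type and 817 ± 209 FPKM in mutants, cpt1ab at 83.4 ± 10.4 and 58.2 ± 12.3 FPKM, and the ribonucleotide reductase gene rrm2 at 20.3 ± 15.8 and 6.70 ± 6.34 FPKM. Higher were macrophage (28 of 29, median 0.85, 9.06e-07, 0 adjusted over the list alone), epicardium (15 of 19, median 0.67, 4.62e-05, 8 adjusted over the list alone), skin and gill epithelium (10 of 12, median 0.82, 0.000907, 2 adjusted over the list alone) and inflammatory mediator genes (28 of 31, median 0.43, 0.00476, 0 adjusted over the list alone). Without the keratins at a mean of 10 FPKM or more, the other 7 skin and gill genes had a median of 0.40, and 0.36 in cryoinjured hearts and 0.38 over both injuries. tcf21, an epicardial and fibroblast transcription factor, was at 24.8 ± 1.55 and 58.2 ± 23.1 FPKM, and the NF-kappaB inhibitor nfkbiaa at 12.3 ± 2.67 and 30.3 ± 9.58 FPKM. The adjusted p of these 8 lists with an estimated correlation was 0.539 to 0.555. The macrophage median was 1.52 without mutant sham 1 and 0.13 without mutant sham 2, the inflammatory median 0.27 without wild-type sham 3 and 0.06 without mutant sham 2, and the epicardial median 1.21 without mutant sham 1 and 0.43 without mutant sham 3. The cell cycle median was -0.07 without mutant sham 1 and -0.99 without mutant sham 2, -0.27 and -0.72 without wild-type sham 1 and 3, and -0.26 without mutant sham 3. The sarcomere and fatty acid oxidation medians were -0.34 and -0.23 without mutant sham 1, and the oxidative phosphorylation median -0.53 without mutant sham 3. Ribosomal protein genes were called higher (76 of 77, median 0.59, 9.28e-14, 0 adjusted over the list alone, 0.555 with an estimated correlation), but stood at 0.15 without mutant sham 1 (adjusted p 0.423). The matrix genes (median 0.51, 0.000975, 0 adjusted over the list alone, 0.662 with an estimated correlation) stood at -0.24 without mutant sham 2 (adjusted p 0.596) and 0.27 without wild-type sham 3 (0.0633), but at 1.25 without mutant sham 1 (3.82e-12) and 0.78 without wild-type sham 2.

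In cryoinjured hearts the genes with the lowest p between genotypes included 3 that were lower in mutants. hhatlb was at 6.94 ± 2.53 FPKM in wild type and 0.06 to 1.1 FPKM in the mutant libraries, the ubiquitin ligase subunit gene asb15b at 5.64 ± 2.37 and 0.927 ± 0.664 FPKM, and epb41l3a, of the membrane skeleton, at 2.3 ± 0.766 and 0.28 ± 0.236 FPKM. krt15 was at 387 ± 99.9 and 875 ± 133 FPKM (1.2 ± 0.24 log2, SE, limma adjusted p 0.873) and vim, encoding the mesenchymal intermediate filament vimentin, at 25.9 ± 3.68 and 71.3 ± 20.7 FPKM (1.39 ± 0.30). None of these 5 passed. limma called 0 genes, against 703 at an unadjusted p under 0.05 (171 higher and 532 lower), where 698 would be expected by chance. The median of all genes was -0.11.

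Of 14 list calls in cryoinjured hearts, 12 were higher and 2 lower in mutants, and 6 held without each single library. Cell cycle genes were lower (40 of 41, median -0.69, adjusted p 2.17e-05, 0.830 with an estimated correlation), among them the mitotic kinesin gene kif23 at -0.92 ± 0.44 and mcm6, of the replicative helicase, at -1.0 ± 0.49. Higher were ribosomal proteins (76 of 77, median 0.51, 1.19e-28, 0.516 with an estimated correlation; median 0.20 without mutant cryoinjury 2), inflammatory mediators (24 of 31, median 0.48, 1.8e-08, 0.259 with an estimated correlation), neutrophil genes (15 of 17, median 0.36, 6.06e-07, 0.259 with an estimated correlation), macrophage genes (26 of 29, median 0.32, 6.2e-06, 0.830 with an estimated correlation), and skin and gill epithelium (10 of 12, median 0.46, 2.02e-05, 0.259 with an estimated correlation). Adjusted over the list alone, 2 skin and gill genes passed and 0 of the other 5 lists. ctssb.1, a lysosomal cathepsin gene, was at 10.2 ± 4.73 FPKM in wild type and 26.2 ± 12.8 FPKM in mutants, and the prostaglandin synthase gene ptgs2a was higher by 1.01 ± 0.37. The inflammatory median was 0.29 without wild-type cryoinjury 2 or mutant cryoinjury 2 and 0.73 without mutant cryoinjury 3, and the macrophage median 0.12, 0.10 and 0.53 without these. The neutrophil median was 0.63 without mutant cryoinjury 3 and the skin median 0.27 without wild-type cryoinjury 1. Fatty acid oxidation genes were called lower (27 of 31, median -0.47, 0.000140, 0.830 with an estimated correlation, 0 adjusted over the list alone), with acsl1b, which activates long-chain fatty acids, at 29.2 ± 10.2 and 10.5 ± 5.95 FPKM, but stood at -0.12 without mutant cryoinjury 2 (adjusted p 0.239) and at -0.77 without mutant cryoinjury 3 (1.14e-07). tagln was lower in mutants by -1.38 ± 0.39, 1 of 3 smooth muscle genes passing when adjusted over a list that was not called (median -0.11, 0.903).

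Over both injuries, krt15 rose in mutants by 1.40 ± 0.17 (log2, SE, limma adjusted p 0.0461, 6 libraries against 6 without overlap) and was the 1 gene called, with 1350 at an unadjusted p under 0.05 (643 higher and 707 lower). Its adjusted p was above the threshold without each library except mutant cryoinjury 3, at 0.0636 to 0.171, while its log2 difference stayed between 1.29 and 1.48. It was also above the threshold with median-of-ratios or TPM rescaling, the replicate block, robust moderation, or mutant sham 1 and 2 both left out (0.0513 to 0.336), and 15 genes were called with array weights. Without wild-type sham 1, wild-type sham 3 or mutant sham 3, 1 gene other than krt15 was called, without mutant cryoinjury 3, 5 were, and without any other single library 0 were. Other keratins stood higher too, krt94 by 1.36 ± 0.24 (0.192) and krt8 by 0.91 ± 0.20 (0.226), and vim by 1.35 ± 0.21 (0.132). The myosin light chains myl9a and myl9b went from 1024 ± 145 to 444 ± 163 FPKM and from 389 ± 42.6 to 213 ± 35.6 FPKM in sham hearts, and over both injuries differed by -1.25 ± 0.24 and -0.86 ± 0.17 (0.195 each). smtnb, a smoothelin gene, differed by -1.77 ± 0.31 (0.192), slc16a1a by -2.40 ± 0.34 (0.0953), hhatlb by -1.93 ± 0.30 (0.132) and asb15b by -1.48 ± 0.24 (0.146). smtnb lies outside the naming rule and was chosen after its values were seen. In 94 genes the 6 mutant libraries did not overlap the 6 wild-type ones, 34 higher and 60 lower, or 0.673% of those tested against 0.216% by chance. For cryoinjury against sham the number was 69, 60 of them higher.

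**Figure D5:**
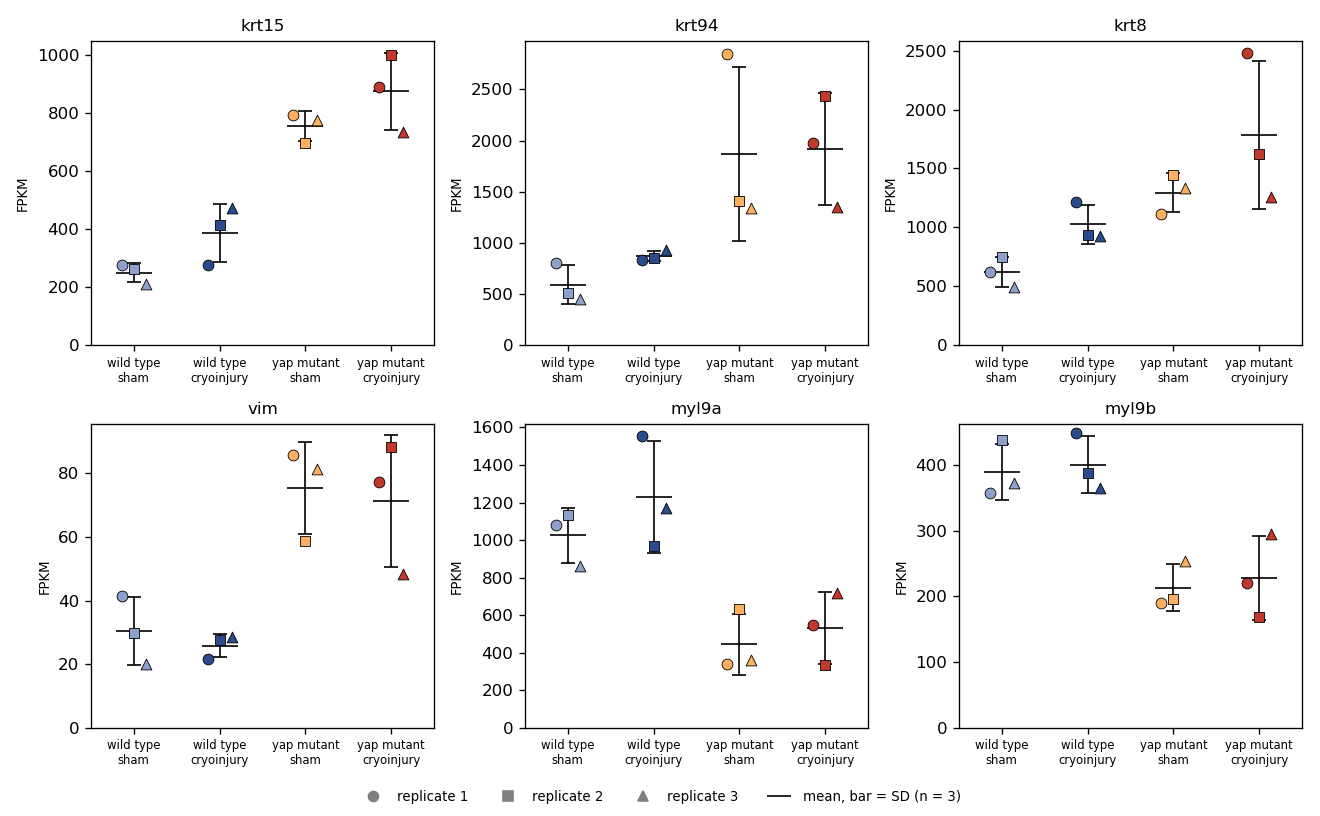
FPKM of krt15, krt94, krt8, vim, myl9a and myl9b in each library by group; points are libraries, bars are means with SD, n = 3. For krt15 the wild-type sham and cryoinjury means are 249.8 and 387 FPKM and the mutant ones 756 and 875 FPKM.

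Over both injuries 21 of 30 lists were called, 14 higher and 7 lower in mutants, and 12 of these calls held without each single library. Higher were ribosomal proteins (median 0.56, adjusted p 2.12e-26), macrophage (0.52, 4.28e-08), inflammatory mediators (0.52, 4.25e-07), pan-leukocyte (0.45, 2.34e-06), skin and gill epithelium (0.54, 2.12e-05), neutrophil (0.22, 0.000169), epicardium (0.37, 0.000169) and complement genes (0.64, 0.00486). Lower were fatty acid oxidation (-0.46, 7.95e-08), cell cycle (-0.56, 1.2e-07), oxidative phosphorylation (-0.25, 2.83e-07) and sarcomere genes (-0.40, 1.8e-06). Adjusted over the list alone, 5 epicardial, 5 higher and 1 lower skin and gill, 3 neutrophil, 2 complement, 1 macrophage and 2 fatty acid oxidation genes passed, and 0 of the other 6 lists. cpt1ab was lower by -0.66 ± 0.16 and igf2b, an insulin-like growth factor gene of the regeneration list, higher by 1.08 ± 0.25. With an estimated correlation 0 of the 30 lists were called (adjusted p 0.313 to 0.581 for these 12). Without mutant sham 1 and without mutant sham 2 in turn, the macrophage median was 0.87 and 0.23 and the pan-leukocyte median 0.73 and 0.17. Without mutant sham 1 the ribosomal median was 0.33, the cell cycle median -0.35, the neutrophil median 0.46 and the epicardial median 0.60. Leaving out 1 library at a time always kept mutant sham 1 or mutant cryoinjury 2. Relative to wild-type sham, ribosomal genes averaged 1.39 and 1.08 (log2) in these 2 and 0.09 to 0.28 in the other mutant libraries. Fatty acid oxidation stood at -1.09 and -1.55 against -0.70 to -0.11, and sarcomere at -0.86 and -0.87 against -0.33 to 0.02. These list calls lean on those 2 libraries. Targets of Yap and Taz were not called (16 of 26 higher, median 0.15, adjusted p 0.288), with 3 higher and 2 lower when adjusted over the list alone. nuak2 was among the 3 higher in mutants, by 0.64 ± 0.14. The 2 lower were myl9a and myl9b, at -1.25 ± 0.24 and -0.86 ± 0.17. Hippo pathway components stood at -0.16 (0.125), with 1 higher and 1 lower when adjusted over the list alone.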

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

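The list tests of the difference between the injury responses were planned, and leaving out single libraries list by list was chosen after these results were seen. By camera, 8 lists differed between the injury responses of mutants and wild type, and with an estimated correlation 0 did (adjusted p 0.740 to 0.915). Sarcomere and calcium handling (median 0.213), oxidative phosphorylation (0.194) and skeletal muscle genes (0.352) were called on the positive side, where the mutant response was less negative or more positive, and all 3 calls were kept without each single library. The skeletal muscle median ranged from 0.147 without mutant sham 1 to 0.974 without mutant cryoinjury 2, the sarcomere median from 0.0281 without mutant sham 1 to 0.468 without mutant cryoinjury 2, and the oxidative phosphorylation median from 0.0189 without mutant cryoinjury 3 to 0.355 without mutant sham 3. With mutant sham 1 and 2 both left out, the sarcomere and oxidative phosphorylation medians turned, to -0.07 and -0.12, and neither list was called (adjusted p 0.150 and 0.359). Glycolysis genes had a median of 0.269 (adjusted p 1.99e-05, 0.0738 without mutant sham 2), which was 0.117 without mutant sham 1 and 0.473 without mutant sham 3. Fatty acid oxidation genes were not called (median -0.0885).

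Fibrillar matrix genes had a median of -0.734 (adjusted p 0.0360), that is, the mutant response was smaller. The call ended without wild-type cryoinjury 1 (0.193), wild-type sham 3 (0.271), mutant cryoinjury 2 (0.145) or 3 (0.0668), mutant sham 2 (0.855, median -0.02) or mutant sham 3 (0.135), and was stronger without mutant sham 1 (median -1.40, adjusted p 6.78e-08). Neutrophil genes had a median of 0.0389 (0.311 without mutant sham 2, -0.0179 without wild-type cryoinjury 2, -0.0904 without mutant sham 1, and -0.00198 with TPM rescaling) and a mean of 0.39 (adjusted p 0.00856, and 0.0772, 0.357 and 0.0768 without wild-type cryoinjury 2, mutant cryoinjury 2 and mutant sham 1). Inflammatory mediators had a median of 0.116 (0.419 without mutant sham 2, but below 0 without wild-type sham 2, mutant cryoinjury 1 or 2, or mutant sham 1 or 3, at -0.153 to -0.0113), a mean of -0.03 and an upward call (adjusted p 0.0463), which ended without any of wild-type cryoinjury 1 or 2, wild-type sham 2 or 3, mutant cryoinjury 1 or 2, and mutant sham 1 or 3 (adjusted p 0.0686 to 0.598). Ribosomal protein genes had a median of -0.0603, which was 0.14 with median-of-ratios rescaling, and an upward call (adjusted p 0.0322). It ended without wild-type cryoinjury 2 (0.347), wild-type sham 1 (0.113) or mutant sham 3 (0.839) and turned downward without mutant cryoinjury 2 (0.00525) or mutant sham 2 (0.00218), and was stronger without mutant sham 1 (median 0.358, adjusted p 4.77e-28).

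Other divisions of the libraries did as much. Of 100 drawn regroupings of genotype within injury, 79 gave at least the 8 lists of the real one, and the highest other gave 18, so chance was not excluded. For genes the real number was 0, which all 100 reach whatever the data, so that count says nothing about chance. The highest other regrouping called 60 genes, which points to a structure of the samples.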

How the results depend on the processing

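Robust moderation, the omission of mutant sham 1 and 2 together, the exact permutation of list means, and all alternatives of the injury response over both genotypes were added after the data were seen; the other alternatives were planned. Where a count moved and no reason is given, the cause was not tested. In wild type 8 genes passed instead of 0 with only the 2 groups compared, 409 with array weights and 34 with both mutant sham libraries left out; array weights and that omission both lower the share of mutant sham 1 and 2 in the spread. In mutants 3 passed with no filter, and 1 each with median-of-ratios rescaling and quantile normalization. No filter gave 1 gene for the genotypes in cryoinjured hearts, 1 for the difference of the responses and 3 for the genotypes over both injuries. The last count, 1, was 3 with quantile normalization, 15 with array weights, and 0 with median-of-ratios rescaling, TPM rescaling, the replicate block, both libraries left out, or robust moderation, where krt15 kept a log2 difference of 1.33 to 1.44 and had adjusted p of 0.0513 to 0.336. For injury over both genotypes the count of 9 was 3 with a filter at 5 FPKM, 19 with median-of-ratios rescaling, 21 with quantile normalization, 3 with the replicate block, 290 with array weights and 29 with both libraries left out.

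Without single libraries the counts ranged from 0 to 18 in wild type, 0 to 3 in mutants, 0 to 2 for the genotypes in sham hearts, 0 to 0 in cryoinjured hearts, 0 to 1 for the difference, 0 to 5 for the genotypes over both injuries and 1 to 428 for injury over both genotypes. Called lists ranged over 11 to 18, 13 to 20, 12 to 17, 11 to 17, 6 to 10, 16 to 21 and 17 to 22 in the same order. With an estimated correlation and with fry 0 lists were called in each of the 7 contrasts, and with an exact permutation of list means 0 in the contrasts over both injuries and over both genotypes. The permutation could not call a single list alone, because its smallest possible p of 0.005 does not pass adjustment over 30 lists. The yap1 difference ranged from -1.05 to -0.873 and the correlation of the injury responses from 0.238 to 0.563.

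The replicate numbers did not pair the samples. Over 18 pairs of groups' same-numbered libraries, correlations of deviations ran from -0.205 to 0.326, 3 were over 0.1, and 4 of 12 libraries matched their own number best. Apart from both counts given, the replicate block changed no count of genes.

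Over 99 gene values followed and 23 alternatives, 2040 of 2214 kept direction and side of the threshold, 99 fell short of it, 49 came to pass it and 26 reversed. All reversals concerned yap1 or wwtr1 differences near 0. For yap1 after injury they were -0.138 (median-of-ratios) and -0.0503 (quantile) in wild type, -0.0385, -0.0177, -0.133 (array weights) and -0.154 (both libraries left out) in mutants, and -0.0882, -0.0340, -0.0451 and -0.0276 over both genotypes. For the difference of the responses they were 0.0994 and 0.0326 for yap1, and 0.0703 and 0.0496 for wwtr1, with median-of-ratios and quantile scaling. Without single libraries yap1 after injury ranged from -0.0923 to 0.228 in wild type, -0.152 to 0.0806 in mutants and -0.0450 to 0.115 over both genotypes, and wwtr1 from -0.0141 to 0.305 in mutants. wwtr1 between genotypes in sham hearts ranged from -0.244 to 0.0533, and the difference of the responses from -0.251 to 0.0947 for yap1 and -0.270 to 0.0498 for wwtr1. Depth differed by less than 2-fold between libraries, and genes near 1 FPKM are limited by it.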

Other observations

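Tests of the 3 patterns weighed here were chosen after the patterns were seen, and the counts over other divisions of the libraries were planned. Globin made up 30.7% of FPKM in wild-type sham 3 and 3.84% in wild-type sham 1. The exocrine pancreas gene ctrb1, of chymotrypsinogen, was at 100.7 ± 129 FPKM (SD, n = 3) in wild-type sham hearts and 1.25 ± 0.97 FPKM in mutant sham hearts, a spread of single libraries. lyve1a, a marker of lymphatic vessels, stood at 1.60 ± 1.64 FPKM in wild-type sham and 6.71 ± 3.07 FPKM in mutant sham hearts, and at 1.44 ± 0.731 and 4.58 ± 3.28 FPKM after cryoinjury. Both fall under the naming rule and were picked among its genes after their values were seen.

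Mutant sham 2 had the expression of an injured heart over most injury genes, though not all. Over 100 wild-type injury genes its median position between wild-type sham (0) and wild-type cryoinjury (1) was 1.05, against -0.206 and 0.358 in the other mutant sham libraries and 0.889 to 0.990 in the cryoinjured mutants. The tables argue against a swap with a cryoinjured mutant library, since the lowest of those 3 still lay at 0.889, and against scaling, since its macrophage excess was 1.48 after median-of-ratios rescaling and 1.93 before. A mislabelled sample, with its partner outside these 12, could give the position of 1.05. Surgical damage or inflammation in mutant sham 2 could also give it, which was not tested. Some injury genes stayed near the sham level in it, such as nupr1 at 7.78 FPKM and lipg at 0.88 FPKM. Genes called over all libraries are selected for that. Of 100 injury genes chosen without it, 13 lay nearer the sham level and 87 nearer the cryoinjured one. Among genes called without it, csf1a stood at 0.79 FPKM (0.815 in the other sham and 3.82 in the cryoinjured libraries). lifrb stood at 1.21 FPKM (1.36 and 5.49), while mdka stood at 383 FPKM (50.6 and 386).

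Mutant sham 1 and mutant cryoinjury 2 had a high share of ribosomal protein mRNA, 38.8% and 32.0%. Lower depth was excluded, as the lower of their relative depths was 1.08 against a median of 1.05. A few genes crowding out the rest gave at most 11.5% of the rise. A preference for short transcripts cannot be told apart from a smaller share of muscle, because the short respiratory chain mRNAs, which it would lift, had medians below the other 10 libraries (the higher by -0.286) while sarcomere genes lay lower still (-0.691 and -0.699), so that a lift of these muscle-rich mRNAs would be hidden. RNA quality, growth state and cell make-up of these hearts stay open and were not tested.

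Over both injuries the 7 tested keratins on the lists with a mean of 10 FPKM or more were all higher in mutants, with a median of 1.36, and summed to 5071 ± 1157 FPKM in mutants and 2304 ± 674 FPKM in wild type (SD, n = 6). Libraries of the genotypes did not overlap for krt15, krt93 and krt94, but did for krt4, krt8, krt18 and krt91. krt91 stood at 610 and 673 FPKM in mutant sham 1 and mutant cryoinjury 2. In the other mutant libraries it was at 97.4 to 216 FPKM, and in wild type at 28.8 to 217 FPKM. Skin or gill tissue on the mutant samples was argued against, because the low-expressed skin genes summed to 21.6 ± 5.01 FPKM in mutants and 32.1 ± 39.8 FPKM in wild type (15.8 without wild-type cryoinjury 3, which carried that sum and, left out, turns the sign), a difference of -10.5 where the keratins differed by 2768. A larger share of epicardial cells, whose list holds krt8 and krt18, cannot be told apart from a change within cells. In cryoinjured hearts the other epicardial genes had a median of 0.0420 and an upper quartile of 0.555 and went both ways, with a keratin median of 1.09, and in sham hearts the medians were 0.663 and 1.53. A change of keratin expression within epithelial cells of the mutants may also account for the rise and was not tested.

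Other divisions of the same libraries were counted for each number of calls, and each count of divisions includes the real one. For the 4 contrasts of 3 libraries against 3 there are 10 divisions, too few for a share under 0.05. Of genes, wild-type injury gave 0 (highest other 1), mutant injury 0 (highest other 234), the genotypes in sham hearts 0 (highest other 0) and in cryoinjured hearts 0 (highest other 0). Any division reaches 0, so that all 10 did says nothing about chance. The 234 genes came from a division that set mutant sham 1 with mutant cryoinjury 1 and 2, a structure of the samples rather than of the groups. Of lists, wild-type injury gave 15 (5 of 10 divisions as many, highest other 17), mutant injury 16 (1 of 10, highest other 14), the genotypes in sham hearts 16 (1 of 10, highest other 15) and in cryoinjured hearts 14 (2 of 10, highest other 14). Over both injuries, 10 of 100 drawn divisions called as many genes as the 1 of the genotypes (highest other 60), so chance was not excluded. Only the real division, 1 of 100, called the 21 lists (highest other 18), and 4 of 100 had as many genes without overlap as the 94 (highest other 215). Few other divisions reached these 2 counts, but the shares are not adjusted for the number of counts made. The list count rests on the preset correlation of 0.01. An exact permutation of list means called 0 lists (smallest adjusted p 0.225). Its smallest possible p, 0.005, cannot pass for a single list after adjustment over 30 lists, so this 0 decides little. Chance was not excluded for the lists. For cryoinjury against sham, 8 of 100 had as many as the 69 genes without overlap (highest other 352), so chance was not excluded.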
